A study of Rattus norvegicus with 38 samples.

How the data were processed

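Total RNA from the livers of 38 male Fischer F344 rats was labelled with Cy3 and hybridized to Agilent 1-colour rat miRNA arrays by the authors, 1 array per animal. Per the labels, RNA integrity numbers were above 8 and animals were assigned to diets at random. Groups, doses and replicate numbers came from the labels, and no array was left out. The deposited scanner files, made with Feature Extraction 10.5.1.1 per the file headers, hold fluorescence intensity per spot on a linear scale. The authors' value table is deposited in log2 units for 167 of the 350 miRNAs. It equals log2 of the total gene signal minus 1 constant per array, within 0.01 for 99.7% of 6276 values. The constant exceeded log2 of the array's 75th percentile by 0.00607 to 0.129, and the columns' medians were 0.0162 to 0.337. How the 167 miRNAs and the constant were chosen is not given in the sources used here.

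Control spots and spots marked as outliers in the files (2.17% to 6.76% of 7000 spots per array) were left out of the processed signal, and the remaining spots of each of 938 probes were averaged. No spot was saturated, and no probe lost all its spots on an array. Each array was divided by its 75th percentile over the 137 probes detected on all arrays, which was 424 to 1086 signal units. Values under the 5th percentile of detected values were set to that floor (log2 -5.49, or 16.7 signal units on the median array). Each miRNA took its brightest probe. A probe was detected where over 50% of its used spots were well above background, and 16.6% to 28.3% of probes were detected per array. The 129 miRNAs detected on every array of at least 1 group were tested, and 80 of these were detected on all arrays. For a miRNA at the floor on all control arrays and detected on all treated arrays, the fold is given as at least that of the treated mean over the floor, and where only some treated arrays detected it no fold is given. Names follow the files without the species prefix.

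All 38 arrays were fitted with limma 3.58.1 (lmFit and eBayes) in R 4.3.3, with the Benjamini-Hochberg adjusted p under 0.05 in each comparison. The comparisons included each chemical against control and an F test over the 8 differences. Further comparisons were 6 chemicals that cause rat liver tumours (the tumour-causing class) against 2 others, and 2-acetylaminofluorene against the mean of the other 5. The class name refers to liver tumours only and says nothing of tumours elsewhere. The classes are general knowledge, since the labels name carcinogens and non-carcinogens without saying which is which. Lists of miRNAs were tested with limma camera, adjusted over 64 pairs, with a preset correlation of 0.01 and with an estimated one. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15. Group sizes of 3 to 5 limit the precision, and signal over background limits it for the dim miRNAs.

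The miRNAs named per chemical are the up to 10 higher and 10 lower with the largest change among those called, with every treated array on the same side of the control mean. miR-34a, miR-200a, miR-200b, miR-429, miR-122 and miR-21 are named for every chemical. Each class comparison names the 5 highest and 5 lowest called, and each list up to 4 members with the smallest adjusted p. Members called in a list, and miRNAs called with 2 or more chemicals, are also named. The comparisons, the lists, this rule and the alternatives were fixed before the data were examined, except where said otherwise.

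Alternatives were scaling over all probes, normexp background correction with an offset of 50, quantile normalization, the mean of a miRNA's probes, the total gene signal, a lower floor, the authors' table, no filter on dim miRNAs, the miRNAs detected on all arrays, slide as a block, replicate number as a block, only the compared groups, an estimated correlation for the lists, and each array left out in turn. Normexp used the median spot and background signals, since the files hold no mean signal. With no filter, 184 miRNAs at the floor on all arrays were left out and 166 fitted, a choice made after the counts were seen. The arrays lie on 6 slides. Control arrays are on slides 1, 3 and 4, with replicate 1 alone on slide 4, and Monuron and Methapyrilene HCl share no slide with control. Differences within a slide rest on 1 or 2 treated arrays and 1 or 2 control arrays. Some alternatives moved the median difference over all tested miRNAs by more than 0.1. Scaling over all probes moved it from 0.044 to -0.14 for Diethylthiourea, from 0.084 to -0.025 for Phenobarbital, from -0.0043 to -0.33 for 2-acetylaminofluorene and from -0.026 to -0.29 for 2-acetylaminofluorene against the other 5. Normexp moved it from -0.040 to -0.19 for Benzophenone, from 0.0085 to -0.21 for Diethylhexylphthalate, from 0.061 to -0.13 for Monuron, from 0.0996 to -0.30 for Chlorendic Acid, from 0.037 to -0.20 for Methapyrilene HCl, from 0.061 to -0.046 for the tumour-causing class and from -0.026 to 0.093 for the last comparison. The authors' table moved it from 0.084 to -0.071 for Phenobarbital, from 0.037 to -0.17 for Methapyrilene HCl, from -0.0043 to -0.24 for 2-acetylaminofluorene and from -0.026 to -0.16 for the last comparison.

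The pipeline was tested on simulated data of 129 miRNAs with the same groups, 20 times per effect. For each comparison of groups, 8 miRNAs were changed at each of 0.5, 1 and 2 log2 units, with independent noise and no slide structure. Across the 8 chemicals 46.2% to 60% of miRNAs changed by 0.5 log2 units were called, 78.1% to 86.9% of those changed by 1 and 85% to 91.9% of those changed by 2, against 0.524% to 1.1% of unchanged ones. At 1 unit the class comparisons called 90% and 81.9%, and at 2 units the F test called 98.8%. The reference table used here holds names without coordinates, so no genomic positions are given.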

Results

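Liver miRNAs were measured in 38 male Fischer F344 rats, 1 array per animal, after 90 days on a diet with 1 of 8 chemicals or on control diet. The groups were control (n = 5), Diethylthiourea at 2500 ppm (n = 4), Benzophenone at 1250 ppm (n = 5), Phenobarbital at 1000 ppm (n = 3), Diethylhexylphthalate at 12000 ppm (n = 4), Monuron at 1500 ppm (n = 4), Chlorendic Acid at 1250 ppm (n = 4), Methapyrilene HCl at 250 ppm (n = 4) and 2-acetylaminofluorene at 40 ppm (n = 5). Of 350 miRNAs on the array, 90 to 141 were detected per animal, and 129 were tested. Levels are log2 of the signal over each array's 75th percentile, with a floor at -5.49. In control liver miR-122, the abundant miRNA of hepatocytes, had a level of 6.40 ± 0.243 (SD, n = 5) and miR-21 of 2.65 ± 0.247. Near the floor were miR-34a (-5.05 ± 0.36), miR-96 (-4.98 ± 0.191), miR-200a (-5.11 ± 0.23), miR-200b (-4.67 ± 0.18) and miR-429, which was at the floor in all 5 control animals. The number of animals per group limited the precision, and for the dim miRNAs so did the background. With normexp background correction and an offset of 50 signal units, which lies above the floor of 16.7 units, 16 of 85 named calls kept their direction and passed the threshold, 56 kept their direction without passing and 13 changed sign.

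Across the 8 diets 58 of 129 miRNAs differed from control in at least 1 group (limma F test, adjusted p under 0.05). miR-34a, a miRNA transcribed under p53, had the smallest adjusted p (1.98e-20), followed by miR-96 (2.61e-12), miR-221 (2.58e-10) and miR-182 (2.38e-09). miR-107 and miR-375 followed at 1.14e-08, and miR-200a and miR-200b at 3.27e-08. The count was 36 among the 80 miRNAs detected on all arrays and 8 with normexp.

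**Figure D1:**
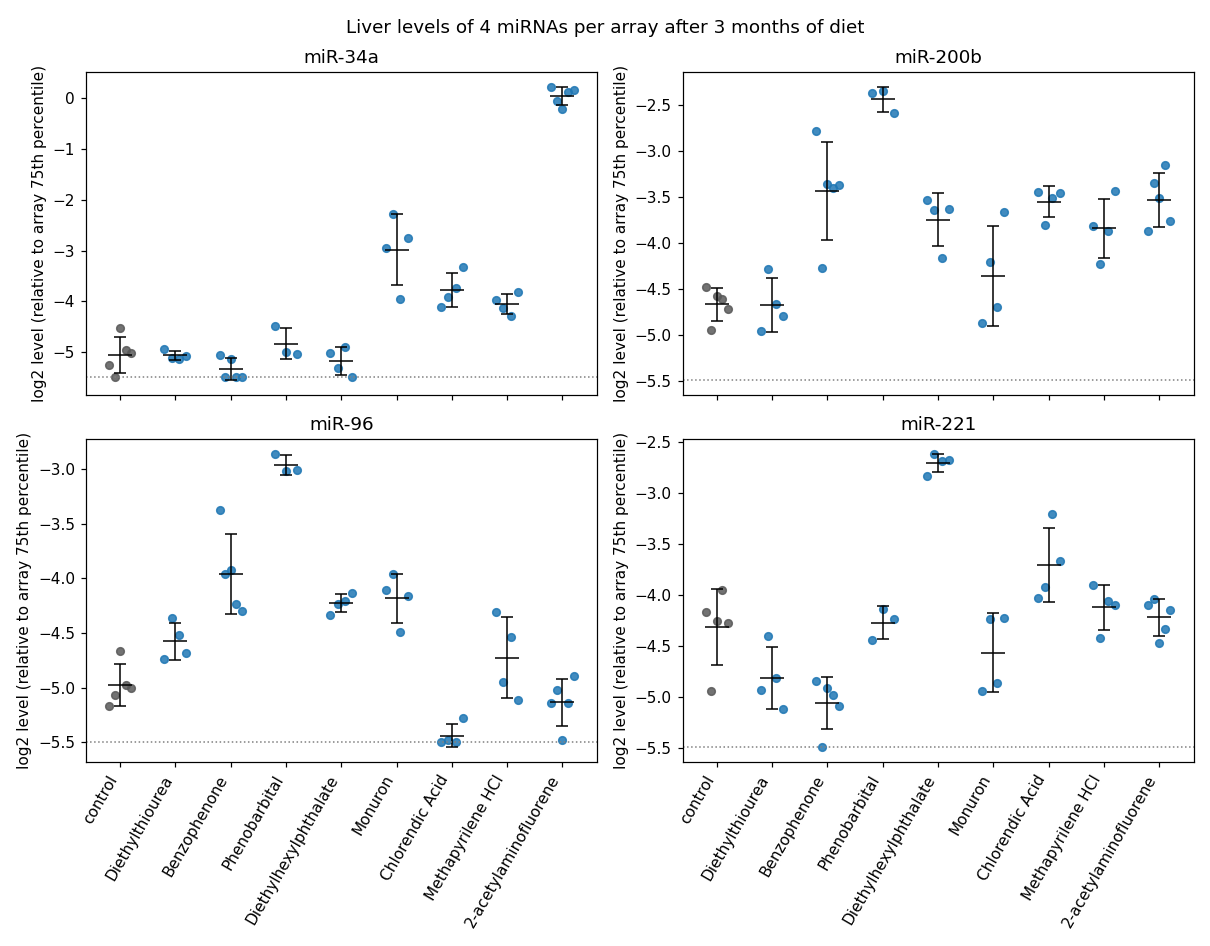
Log2 level per array of miR-34a, miR-200b, miR-96 and miR-221 in the 9 groups, with bars for the mean ± SD and a dotted line at the floor of -5.49. Group means of miR-34a ran from -5.33 with Benzophenone to 0.043 with 2-acetylaminofluorene, and the normexp difference of miR-34a had the opposite sign with Methapyrilene HCl, as did that of miR-96 with Diethylhexylphthalate.

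With Diethylthiourea (n = 4 against 5) no miRNA was called by limma, and 8 had an unadjusted p under 0.05. The differences were log2 -0.0094 ± 0.22 (SE) for miR-34a, -0.15 ± 0.22 for miR-200a and -0.0087 ± 0.22 for miR-200b, each with an adjusted p of 0.993. miR-122 (-0.067) and miR-21 (-0.28) did not pass either, and miR-429 stayed at the floor in both groups. In simulated data 85% of miRNAs changed by 1 log2 unit were called in this comparison, and 53.8% of those changed by 0.5. There 8 miRNAs per size were changed at once with independent noise. The shares may be lower where few miRNAs change.

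Benzophenone raised 4 miRNAs and lowered 2 (n = 5 against 5). miR-200b, an epithelial miRNA, rose 2.35-fold (log2 1.23 ± 0.21 SE, adjusted p = 0.000116) and miR-200a 2.01-fold (1.0 ± 0.21, adjusted p = 0.000855). The other probe of miR-200a differed by log2 0.303, so its size is uncertain. miR-96 rose 2.02-fold (1.02 ± 0.15, adjusted p = 1.02e-05), and miR-182, from the same cluster as miR-96, rose at least 1.5-fold against the floor (log2 0.58, adjusted p = 0.000427), on 1 of its 3 probes. miR-221 fell by 0.75 ± 0.17 log2 (adjusted p = 0.00398) and miR-99a by 0.43 ± 0.11 (adjusted p = 0.00758). miR-34a (-0.28), miR-122 (-0.29), miR-21 (-0.52) and miR-429, detected in 3 of 5 animals, did not pass (adjusted p = 0.69, 0.0628, 0.0608 and 0.312). Within slide 1, the only slide shared with control, the differences were 1.82 for miR-200b, 1.61 for miR-200a, 1.44 for miR-96, 0.90 for miR-182, -0.74 for miR-221 and -0.15 for miR-99a. That slide held 1 Benzophenone array and 2 control arrays.

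In a fit with slide as a block, 5 of the 6 Benzophenone calls remained (miR-200b 1.52, miR-200a 1.31, miR-96 1.16, miR-182 0.75, miR-221 -0.80), and miR-99a did not pass (-0.42, adjusted p = 0.0696), nor did it without Benzophenone replicate 2 (adjusted p = 0.052). The count was 12, with 4 higher and 8 lower, without Benzophenone replicate 1, 2 in a fit of only these 2 groups, 1 among the miRNAs detected on all arrays and 0 with normexp, where miR-182 was at -0.0065. Quantile normalization and the authors' table each gave 5 higher and 1 lower. In 7 of 100 splits of these arrays into 2 groups, the real one included, at least 6 miRNAs were called, with up to 19. Chance is therefore not excluded for the count.

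Phenobarbital, a barbiturate that activates the receptor CAR, raised 5 miRNAs and lowered none (n = 3 against 5, 14 at an unadjusted p under 0.05). miR-200b rose 4.72-fold (log2 2.24 ± 0.24 SE, adjusted p = 8.08e-09), miR-200a 4.24-fold (2.08 ± 0.24, adjusted p = 1.5e-08) and miR-96 4.03-fold (2.01 ± 0.17, adjusted p = 3.72e-11). The other probe of miR-200a differed by log2 1.24. miR-96 lay near the floor in control liver, detected in 3 of 5 control animals. miR-182 rose at least 2.49-fold against the floor (log2 1.32, adjusted p = 7.54e-10) and miR-429 at least 1.94-fold (0.96, adjusted p = 8.8e-06), the former on 1 of its 3 probes. miR-34a (0.21), miR-122 (-0.19) and miR-21 (-0.082) did not pass (adjusted p = 0.707, 0.529 and 0.902). Within slides 1, 3 and 4 miR-200b differed by 2.23, 2.50 and 1.89, miR-200a by 2.23, 2.00 and 2.21, and miR-96 by 1.96, 2.02 and 2.16, and with slide as a block all 5 calls remained (miR-200b 2.24, miR-96 2.01). Each of these slides held 1 Phenobarbital array, with 2, 2 and 1 control arrays. The 5 calls remained without any 1 array. None of the 5 is detected on all arrays, so that set gave a count of 0, as did normexp; the authors' table gave 5 higher and 1 lower.

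Diethylhexylphthalate, a plasticizer that activates PPAR-alpha, raised 14 miRNAs and lowered 5 (n = 4 against 5). miR-221, linked to hepatocyte proliferation, rose 3.06-fold (log2 1.61 ± 0.18 SE, adjusted p = 3.53e-08), and miR-107, encoded in a pantothenate kinase gene, 2.03-fold (1.02 ± 0.11, adjusted p = 1.52e-08). miR-200b rose by 0.92 ± 0.22 (adjusted p = 0.00412), miR-200a by 0.69 ± 0.22 (adjusted p = 0.0297) and miR-96 by 0.75 ± 0.16 (adjusted p = 0.00112). The other probe of miR-200a differed by only 0.0835, so its size is uncertain. Smaller rises were those of miR-93 (0.50), miR-375 and miR-29a (0.44 each), miR-25 (0.39) and miR-152 (0.35), with adjusted p from 0.0017 to 0.0392. miR-375 lay near the floor, detected in 2 of 5 control animals. Of its 2 probes, 1 stayed at the floor in both groups and gave no measure of a difference. The red cell miRNA miR-451 fell by 0.72 ± 0.24 (adjusted p = 0.0426), miR-345-5p by 0.57, miR-99a by 0.40, miR-195 by 0.39 and miR-122 by 0.34 ± 0.10 (adjusted p = 0.0239). miR-34a (-0.13) and miR-21 (-0.32) did not pass (adjusted p = 0.752 and 0.228). miR-429 was near the floor in both groups.

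Of the 19 Diethylhexylphthalate calls 11 remained with slide as a block, all higher, among them miR-221 (1.61), miR-107 (1.08), miR-200b (1.12), miR-200a (0.93) and miR-96 (0.91). miR-25, miR-99a and miR-195 had an adjusted p of 0.0688, and miR-152, miR-451, miR-345-5p and miR-122 of 0.0703. Within slides 3 and 4 the differences were 1.99 and 1.49 for miR-221, 0.88 and 1.44 for miR-107, 1.19 and 0.84 for miR-200b, 0.65 and 1.06 for miR-200a, -0.88 and -0.84 for miR-451, and -0.12 and -0.64 for miR-122. These rest on 1 treated array per slide, against 2 control arrays on slide 3 and only control replicate 1 on slide 4. That control array was low for miR-107 (-1.395, against -0.918 to -0.850 in the other control animals). The count was 8, all higher, without Diethylhexylphthalate replicate 1 and 12 (11 higher) without replicate 2. Scaling over all probes gave 6 higher and 1 lower, normexp 2, and the miRNAs detected on all arrays 11, with 6 higher and 5 lower. With normexp miR-96 was at -0.071, miR-200a at -0.067, miR-93 at -0.0092 and miR-375 at -0.16.

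Of the 15 named calls with Diethylhexylphthalate, 8 each depended on single arrays. miR-200a did not pass without control replicate 1 or 2 or Diethylhexylphthalate replicate 1, 2 or 4 (adjusted p up to 0.0829), and miR-25 without control replicate 1 or any 1 treated array (up to 0.122). Without control replicate 1 the difference of miR-25 was 0.21. miR-451 needed Diethylhexylphthalate replicates 1, 2 and 4 and control replicates 1, 3, 4 and 5 (up to 0.15), and miR-195 the same treated arrays and control replicates 1, 2, 3 and 5 (up to 0.139). miR-345-5p did not pass without treated replicate 1 or 4 or control replicate 2, 3 or 5 (up to 0.108), and miR-122 without treated replicate 1 or 2 or control replicate 1 or 4 (up to 0.0829). miR-152 did not pass without treated replicate 1 or control replicate 3 (up to 0.0772), and miR-99a without treated replicate 1 or 2 (up to 0.0837).

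Monuron, a phenylurea herbicide, raised 4 miRNAs and lowered 1 (n = 4 against 5). miR-34a rose 4.19-fold (log2 2.07 ± 0.22 SE, adjusted p = 8.07e-09) and miR-96 1.73-fold (0.79 ± 0.16, adjusted p = 0.000646). miR-375 was called higher (0.75 ± 0.0976, adjusted p = 6.44e-07) near the floor: only 2 of 5 control animals had it detected. Of its 2 probes, 1 stayed at the floor in both groups and gave no measure of a difference. miR-103 rose by 0.33 (adjusted p = 0.0323), and miR-99a fell by 0.48 ± 0.11 (adjusted p = 0.00546). miR-200a (0.11), miR-200b (0.31), miR-122 (0.012) and miR-21 (-0.35) did not pass (adjusted p = 0.96, 0.563, 0.967 and 0.327), and miR-429 stayed at the floor. No slide held both Monuron and control arrays, so no within-slide value exists. A slide block kept miR-34a (2.06), miR-96 (0.93) and miR-375 (0.87), while miR-103 (0.34, adjusted p = 0.176) and miR-99a (-0.44, adjusted p = 0.144) did not pass. miR-99a did not pass without Monuron replicate 3 (adjusted p = 0.0738), nor miR-103 without any 1 Monuron array or control replicate 1 or 2 (up to 0.124). The count was 3 without Monuron replicate 3 and 3 in a fit of only these 2 groups, 1 among the miRNAs detected on all arrays and 1 with normexp, where miR-375 was at -0.027. Higher and lower counts were 3 and 2 with scaling over all probes and with the authors' table, and 3 and 3 with quantile normalization.

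Chlorendic Acid, a chlorinated dicarboxylic acid, raised 26 miRNAs and lowered 12 (n = 4 against 5). miR-505 rose 2.89-fold (log2 1.53 ± 0.27 SE, adjusted p = 0.000109), miR-34a 2.43-fold (1.28 ± 0.22, adjusted p = 8.3e-05) and miR-200b 2.17-fold (1.12 ± 0.22, adjusted p = 0.000354). miR-139-5p was called higher (1.32 ± 0.20, adjusted p = 2.37e-05), but it was detected in only 2 of 5 control animals, and its 2 probes differed by 1.32 and 0.12, so its size is uncertain. Of the 4 probes of miR-505, 2 stayed at the floor in both groups and gave no measure of a difference. miR-200a (0.96), miR-125a-5p (0.71), miR-146a (0.68), miR-30d (0.66), miR-186 (0.62) and miR-181a (0.61) also rose, with adjusted p from 0.000215 to 0.00664. The other probe differed by only 0.388 for miR-200a, 0.262 for miR-125a-5p and 0.363 for miR-181a. miR-324-3p fell by 2.19 ± 0.57 (adjusted p = 0.00406), miR-193, a liver-enriched miRNA, by 2.17 ± 0.38 (adjusted p = 0.000104) and miR-203 by 0.91 ± 0.17 (adjusted p = 0.000224). Of the miR-17-92 cluster and its paralogs, miR-19b fell by 0.92, miR-20a by 0.62 and miR-17 by 0.58, while miR-25 was called higher (0.46). miR-30b-5p (-0.81), miR-497 (-0.73), miR-210 (-0.51) and miR-96 (-0.46) fell as well. The adjusted p of these 4 and of miR-19b, miR-20a and miR-17 ran from 0.000717 to 0.0417. miR-210 and miR-96 fell to near the floor, detected in 1 and 3 of 4 treated animals. Their other probes differed by only -0.0655 and -0.155, so their sizes are uncertain. miR-429, miR-122 (-0.043) and miR-21 (-0.31) did not pass (adjusted p = 0.387, 0.767 and 0.177). Chlorendic Acid replicate 4 stood apart from its group for miR-193, at -3.17 against -5.49 to -4.91, and for miR-324-3p, at -1.90 against -5.03 to -3.75.

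For Chlorendic Acid 36 miRNAs were called with slide as a block, 31 of them among the 38, with miR-505 at 1.68, miR-34a at 1.25, miR-193 at -2.27 and miR-324-3p at -2.32, while miR-210 did not pass (-0.53, adjusted p = 0.0718). Within slides 1 and 4 the differences were 0.64 and 1.64 for miR-34a, 1.15 and 0.85 for miR-200b, 0.87 and 1.41 for miR-200a, -2.51 and -1.68 for miR-193, -3.02 and -0.34 for miR-324-3p, -1.04 and -0.051 for miR-497, and -0.76 and 0.11 for miR-210. Slide 1 held 1 treated and 2 control arrays, and slide 4 held 2 treated arrays and only control replicate 1. That array was the lowest of the control arrays for 74 of 129 miRNAs. The count was 21 in a fit of only these 2 groups, 18 (9 higher and 9 lower) among the miRNAs detected on all arrays and 7 with normexp, where miR-139-5p (-0.0068), miR-200a (-0.12), miR-186 (-0.081) and miR-181a (-0.22) changed sign. Scaling over all probes gave 20 higher and 15 lower and the authors' table gave 19 higher and 23 lower. Without control replicate 1 miR-30d was at 0.44 (adjusted p = 0.0311). Without Chlorendic Acid replicate 3 neither miR-19b (adjusted p = 0.0774) nor miR-30b-5p (adjusted p = 0.0686) passed. miR-96 did not pass without Chlorendic Acid replicate 1, 2 or 3 or control replicate 3 (up to 0.0823), nor miR-210 without the same treated arrays or control replicate 3, 4 or 5 (up to 0.12).

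Methapyrilene HCl, a withdrawn antihistamine, raised 5 miRNAs and lowered 1 (n = 4 against 5). miR-34a rose 2.00-fold (log2 1.0 ± 0.22 SE, adjusted p = 0.00768), miR-200b by 0.83 ± 0.22 (adjusted p = 0.0273) and miR-200a by 0.83 ± 0.22 (adjusted p = 0.0262). The other probe of miR-200a differed by 0.448. miR-199a-3p rose by 0.61 ± 0.18 (adjusted p = 0.0446) and miR-93 by 0.36 ± 0.11 (adjusted p = 0.0483), and miR-99a fell by 0.45 ± 0.11 (adjusted p = 0.0256). miR-122 (-0.24), miR-21 (-0.29) and miR-429 did not pass (adjusted p = 0.24, 0.399 and 0.759). No slide held both Methapyrilene HCl and control arrays. With slide as a block miR-34a (1.01, adjusted p = 0.0394), miR-200b (1.13, adjusted p = 0.0255) and miR-200a (1.2, adjusted p = 0.0133) remained, while miR-199a-3p (0.73, adjusted p = 0.0937), miR-93 (0.43, adjusted p = 0.107) and miR-99a (-0.42, adjusted p = 0.115) did not pass. In a fit with the number of detected miRNAs per array, miR-200a (0.73) and miR-200b (0.80) each had an adjusted p of 0.0512.

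Each Methapyrilene HCl call was lost without at least 1 array. The count was 0 without Methapyrilene HCl replicate 4, 1 without its replicate 3 or control replicate 2, 2 without its replicate 1 and 3 without control replicate 1. miR-34a did not pass without replicate 4 (adjusted p = 0.0632), miR-200b without replicate 1, 3 or 4 or control replicate 2 (up to 0.133), and miR-99a without replicate 3 or 4 or control replicate 2 (up to 0.0791). miR-200a, miR-199a-3p and miR-93 did not pass without treated replicate 1, 3 or 4 or control replicate 1 or 2 (up to 0.116, 0.256 and 0.218). The count was 12 with the total gene signal, 10 with quantile normalization, 3 higher and 5 lower with the authors' table, 3 without the 3 arrays with the fewest detected miRNAs, and 1 with scaling over all probes (higher) and among the miRNAs detected on all arrays (lower). With normexp it was 0, with miR-34a at -0.036, miR-200a at -0.045 and miR-93 at -0.096.

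With 2-acetylaminofluorene, an aromatic amine that forms DNA adducts, miR-34a rose 34.2-fold (log2 5.10 ± 0.20 SE, adjusted p = 1.56e-20), from near the floor to 0.043 ± 0.184 (SD, n = 5 against 5). In total 12 miRNAs rose and 3 fell. miR-494, from the Dlk1-Dio3 locus, rose 4.0-fold with a wide spread between animals (2.00 ± 0.47, adjusted p = 0.0059, treated SD 0.933). miR-200b (1.14 ± 0.21) and miR-200a (1.12 ± 0.21) rose with an adjusted p of 0.00028 each, and miR-429 was called higher (adjusted p = 0.0101) but detected in only 3 of 5 treated and 0 of 5 control animals, so no size is given. The other probe of miR-200a differed by 0.687. Of the mesenchymal list miR-199a-5p (0.61), miR-199a-3p (0.55) and miR-214 (0.49) rose (adjusted p = 0.0345, 0.034 and 0.0345), while miR-125b-5p fell by 0.46 and miR-99a by 0.44 (adjusted p = 0.0101 and 0.00636). miR-500 (0.72) and miR-181a (0.54) rose (adjusted p = 0.0358 and 0.0182), and miR-10a-5p fell by 0.45 (adjusted p = 0.00987). miR-122 (-0.17) and miR-21 (-0.10) did not pass (adjusted p = 0.277 and 0.782). Within slide 3, the only slide shared with control, the differences were 5.38 for miR-34a, 2.42 for miR-494, 1.69 for miR-200b, 1.39 for miR-200a, -0.74 for miR-125b-5p, -0.57 for miR-99a and -0.055 for miR-500. That slide held 1 treated and 2 control arrays.

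Of the 15 calls with 2-acetylaminofluorene 5 remained with slide as a block: miR-34a (5.08), miR-200a (1.39), miR-200b (1.34), miR-429 and miR-125b-5p (-0.52). miR-494 (1.53), miR-199a-5p, miR-199a-3p, miR-181a and miR-99a had an adjusted p of 0.105, miR-500 of 0.128, miR-10a-5p of 0.14 and miR-214 of 0.258. The split between higher and lower turned with the scaling: 5 and 48 over all probes, 6 and 6 with quantile normalization, and 6 and 27 with the authors' table, where the median over all miRNAs moved from -0.0043 to -0.33 over all probes and to -0.24 in the authors' table. The count was 8 in a fit of only these 2 groups, 6 (3 higher and 3 lower) among the miRNAs detected on all arrays and 3 with normexp. miR-500 did not pass without 2-acetylaminofluorene replicate 2, 3 or 5 or control replicate 1, 2, 3 or 4 (adjusted p up to 0.156), and miR-214 without treated replicate 2 or 3 or control replicate 3, 4 or 5 (up to 0.159). miR-199a-5p did not pass without treated replicate 2, 3 or 5 or control replicate 1 (up to 0.127), miR-199a-3p without treated replicate 2 or 4 or control replicate 1 or 2 (up to 0.104), and miR-181a without control replicate 1 (0.0624).

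**Figure D2:**
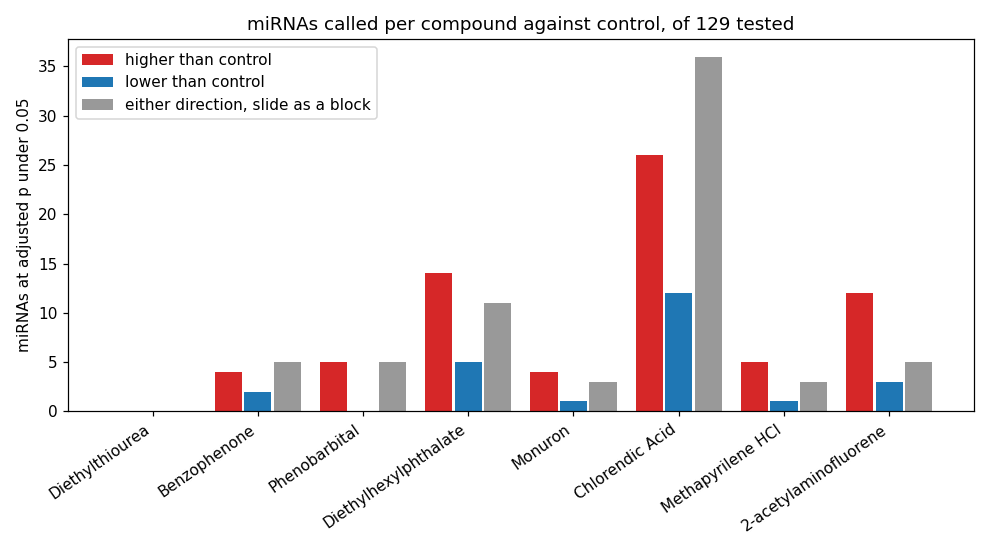
Number of miRNAs called higher and lower against control for each chemical, and the total with slide as a block. The totals with slide as a block were 5 for Benzophenone, 5 for Phenobarbital, 11 for Diethylhexylphthalate, 36 for Chlorendic Acid and 5 for 2-acetylaminofluorene.

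Several miRNAs were called with more than 1 chemical. miR-200a and miR-200b were higher with 6 (Benzophenone, Phenobarbital, Diethylhexylphthalate, Chlorendic Acid, Methapyrilene HCl and 2-acetylaminofluorene). These differences kept their sign under each scaling. With normexp none of them passed, and miR-200a was negative with Diethylhexylphthalate (-0.067), Chlorendic Acid (-0.12) and Methapyrilene HCl (-0.045). miR-99a was lower with 6 (Benzophenone, Diethylhexylphthalate, Monuron, Chlorendic Acid, Methapyrilene HCl and 2-acetylaminofluorene). miR-34a was higher with 4 (Monuron, Chlorendic Acid, Methapyrilene HCl and 2-acetylaminofluorene). miR-96 was higher with 4 (Benzophenone, Phenobarbital, Diethylhexylphthalate and Monuron) and lower with Chlorendic Acid. miR-182, miR-375 and miR-93 were higher with 3 each, and miR-103, miR-128, miR-152, miR-181a, miR-185, miR-199a-3p, miR-221, miR-25, miR-342-3p and miR-429 with 2 each. In total 17 miRNAs were higher and 1 lower with at least 2 chemicals. All 8 comparisons share the 5 control animals: simulated groups with no effect gave a mean of 0.17 such miRNAs and a highest of 12, and independent lists of these lengths would give 11.9 higher and 1.43 lower. The count was 8 higher and 0 lower with slide as a block, 8 in fits of only the compared groups, 2 (1 higher and 1 lower) among the miRNAs detected on all arrays and 1 with normexp. Higher and lower counts were 9 and 10 with scaling over all probes, 16 and 6 with quantile normalization and 9 and 9 with the authors' table.

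**Figure D3:**
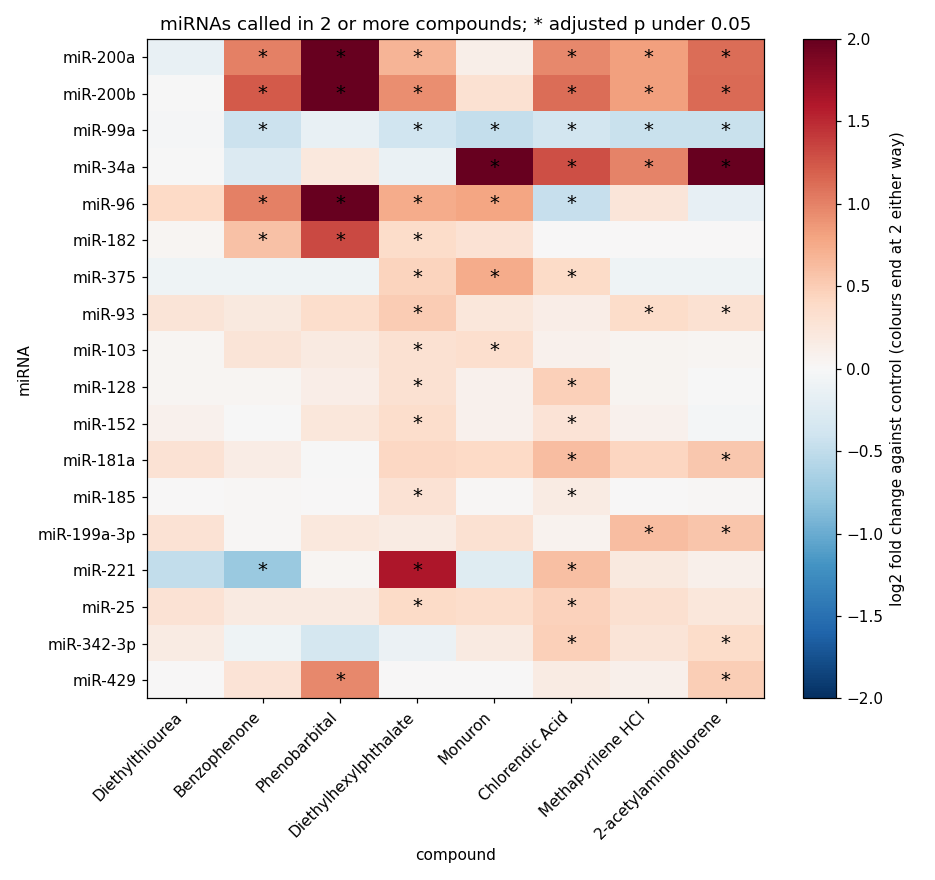
Log2 difference from control of the 18 miRNAs called in the same direction with at least 2 chemicals, with the colour scale ending at 2 and -2 and a star for an adjusted p under 0.05. miR-34a with 2-acetylaminofluorene (5.10) lies beyond the scale, and miR-96 was at 2.01 with Phenobarbital and -0.46 with Chlorendic Acid.

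The 6 chemicals known to cause rat liver tumours (Phenobarbital, Diethylhexylphthalate, Monuron, Chlorendic Acid, Methapyrilene HCl and 2-acetylaminofluorene) were set against Diethylthiourea and Benzophenone; these classes are general knowledge, and the error is between animals, not between chemicals. With 8 miRNAs higher and none lower in the tumour-causing class, miR-34a differed by log2 1.73 ± 0.13 SE (adjusted p = 7.84e-13), miR-221 by 1.01 ± 0.11 (8.07e-09), miR-200a by 0.54 ± 0.13 (0.00634), miR-200b by 0.48 ± 0.13 (0.0177) and miR-375 by 0.30 ± 0.0573 (0.000373). For miR-34a the single effects were 5.10 with 2-acetylaminofluorene, 2.07 with Monuron, 1.28 with Chlorendic Acid and 1.0 with Methapyrilene HCl, but 0.21 with Phenobarbital and -0.13 with Diethylhexylphthalate, which did not pass. miR-375 was at 0.75 with Monuron, 0.44 with Diethylhexylphthalate and 0.38 with Chlorendic Acid. It stayed at the floor with Phenobarbital, Methapyrilene HCl, Diethylthiourea and Benzophenone and at or near it with 2-acetylaminofluorene, so its class difference rests on 3 chemicals and has no exact size. For miR-221 the single effects were 1.61 with Diethylhexylphthalate and 0.61 with Chlorendic Acid against -0.75 with Benzophenone and -0.50 with Diethylthiourea, and -0.25 with Monuron. miR-200a and miR-200b were highest with Phenobarbital (2.08 and 2.24), and in the other class were at 1.0 and 1.23 with Benzophenone, against 0.69 and 0.92 with Diethylhexylphthalate. miR-200b did not pass without Benzophenone replicate 2 (adjusted p = 0.0595), Diethylthiourea replicate 1 (0.0709) or Diethylthiourea replicate 4 (0.055), and the count was 5 without Diethylthiourea replicate 1. It was 12 without Benzophenone replicate 1, 14 with the total gene signal, 5 with scaling over all probes, 2 among the miRNAs detected on all arrays and 1 with normexp. Quantile normalization gave 5 higher and 2 lower and the authors' table gave 5 higher and 8 lower.

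2-acetylaminofluorene, the DNA-reactive chemical among the 6 by general knowledge, was compared with the mean of the other 5 (n = 5 against 19), and 16 miRNAs were higher and 26 lower. miR-34a was higher by log2 4.21 ± 0.16 SE (adjusted p = 5.01e-21), miR-494 by 2.45 ± 0.38 (1.05e-05), miR-188 by 1.69 ± 0.34 (0.000441), miR-212 by 0.95 (0.00819) and the leukocyte miRNA miR-142-3p by 0.88 (0.00618). miR-505 was lower, at -1.17 ± 0.20 (adjusted p = 7.46e-05), as were miR-96 at -0.83 ± 0.12 (3.12e-06), miR-333_v11.0 at -0.84 (0.0454), and miR-126* and miR-92a at -0.53 each (0.0117 and 0.0148). For miR-505 and miR-96 other chemicals gave most of the gap: against control miR-505 was at 1.53 with Chlorendic Acid and -0.43 with 2-acetylaminofluorene. miR-96 was at 2.01 with Phenobarbital, 0.79 with Monuron, 0.75 with Diethylhexylphthalate, 0.25 with Methapyrilene HCl, -0.46 with Chlorendic Acid and -0.16 with 2-acetylaminofluorene. Against control 2-acetylaminofluorene was at 1.19 for miR-188, 0.47 for miR-212, 0.78 for miR-142-3p, -0.60 for miR-333_v11.0, -0.54 for miR-126* and -0.38 for miR-92a, and none of these 6 passed. A slide block gave 7 higher and 17 lower, and miR-92a did not pass (-0.36, adjusted p = 0.0645). Without 2-acetylaminofluorene replicate 3 the count was 20, with 7 higher and 13 lower, and neither miR-126* (adjusted p = 0.0568) nor miR-92a (0.0753) passed. miR-333_v11.0 did not pass in 15 of the fits that each left out 1 array (adjusted p up to 0.24). The split was 5 higher and 59 lower with scaling over all probes, 9 and 33 with quantile normalization and 10 and 37 with the authors' table. The count was 19 among the miRNAs detected on all arrays and 7 with normexp.

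Of 18 miRNA lists, 8 had at least 3 tested members, and 8 of the 64 list and chemical pairs passed (limma camera with a preset correlation of 0.01). The miR-200 family (miR-200a, miR-200b and miR-429) was higher with Phenobarbital, with a mean of log2 1.76 (adjusted p = 2.02e-08, adjusted p = 0.0063 with an estimated correlation) and all 3 members called higher, also when adjusted over the list alone. It was higher with Benzophenone (mean 0.84, adjusted p = 4e-05, adjusted p = 0.0698 with an estimated correlation), with 2 of 3 members called and 3 when adjusted over the list alone. With 2-acetylaminofluorene it was at 0.92 (adjusted p = 0.00431, adjusted p = 0.366 with an estimated correlation), with 3 of 3 called and 3 adjusted over the list alone. With Methapyrilene HCl it was at 0.585 (adjusted p = 0.0482, adjusted p = 0.538 with an estimated correlation), with 2 of 3 called and 2 adjusted over the list alone. The family did not pass with Diethylhexylphthalate (adjusted p = 0.233, 2 of 3 members higher), Chlorendic Acid (0.137, 2 of 3 higher), Monuron (0.951) or Diethylthiourea (0.539). Its mean with slide as a block was 1.77 with Phenobarbital, 1.1 with Benzophenone, 1.14 with 2-acetylaminofluorene and 0.89 with Methapyrilene HCl, and within slides it was 1.81, 1.87 and 1.64 with Phenobarbital, 1.43 with Benzophenone and 1.30 with 2-acetylaminofluorene.

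The list of miRNAs linked to liver proliferation was higher with Diethylhexylphthalate (mean log2 0.43, adjusted p = 0.00561, adjusted p = 0.538 with an estimated correlation), with 5 of 10 members called higher, miR-221, miR-96 and miR-93 among them, and 5 adjusted over the list alone. It was higher with Phenobarbital (0.46, adjusted p = 0.0135, adjusted p = 0.538 with an estimated correlation) through miR-96 and miR-182, with 2 of 10 called and 3 adjusted over the list alone. The list of 10 liver-enriched miRNAs passed as a set with Methapyrilene HCl, with a negative mean (-0.21, adjusted p = 0.0112, adjusted p = 0.497 with an estimated correlation), with 0 members called by limma and 0 adjusted over the list alone. The list of 5 leukocyte miRNAs passed as a set with Diethylthiourea, with a positive mean (0.24, adjusted p = 0.0259, adjusted p = 0.497 with an estimated correlation), with 0 members called and 0 adjusted over the list alone. This last pair did not pass with slide as a block (0.25, adjusted p = 0.114), and within slides 1 and 4 its mean was 0.029 and 0.73. The only control array on slide 4 was replicate 1, which was low for miR-146a (-2.08, against -1.16 to -0.96 in the other control animals). The proliferation list was at 0.49 with Diethylhexylphthalate and 0.47 with Phenobarbital with slide as a block, at 0.30 and 0.73 within slides 3 and 4 for the former and at 0.49, 0.37 and 0.69 within slides 1, 3 and 4 for the latter, and the liver-enriched list was at -0.22 with Methapyrilene HCl. Quantile normalization gave 4 passing pairs, all higher, and the 80 miRNAs detected on all arrays gave 0.

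The other 4 lists passed with no chemical. In the miR-17-92 list (8 tested) miR-25 was higher and miR-17, miR-20a and miR-19b lower with Chlorendic Acid (adjusted p = 0.258), and miR-93 and miR-25 were higher with Diethylhexylphthalate (0.491). In the let-7 family (10 tested) let-7i and let-7d* were higher with Chlorendic Acid (0.26). In the miR-29 family (4 tested) miR-29a was higher with Diethylhexylphthalate (0.137), and miR-29b was lower with Chlorendic Acid (0.26). The mesenchymal list (9 tested) had miR-199a-5p, miR-199a-3p and miR-214 higher and miR-99a and miR-125b-5p lower with 2-acetylaminofluorene (0.951), and with Monuron its median was 0.052 while its mean (-0.017) and test pointed down (0.234). Of the leukocyte list, miR-146a, miR-342-3p and miR-150 were higher with Chlorendic Acid without the list passing (0.234). Lists with fewer than 3 tested members were represented by miR-34a (miR-34 family), miR-494 (Dlk1-Dio3 locus), miR-181a, miR-221, miR-96 and miR-182, miR-126 and miR-126* (endothelial), miR-16 and miR-451 (red cell), 2 members of the cluster of miR-322 and miR-503 and miR-1* (muscle), and no neural miRNA was tested.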

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

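Chosen only after the result was seen were the tests against Diethylthiourea and with slide for miR-200a and miR-200b, those with slide and scaling for miR-34a, and that of swapped arrays, whose prediction was made stricter after its value was seen; the threshold for untested miRNAs was also set after the counts were seen.

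In 12 of 123 groups 1 animal lay far from the others, where chance gives about 1 in 20, or 6.15. The values are that animal's gap to the nearest other as a share of the group's range. Control replicate 1 was the lowest in 8 of these: miR-99a (0.716), miR-107 (0.874), miR-29a (0.746), miR-25 (0.845), miR-146a (0.823), miR-181a (0.781), miR-497 (0.763) and miR-199a-5p (0.841). It was the lowest of the 5 control animals for 74 of 129 miRNAs, with a median deviation of log2 -0.26. The others were miR-29a highest in Diethylhexylphthalate replicate 3 (0.906), miR-122 highest in Chlorendic Acid replicate 3 (0.863), miR-93 lowest in Methapyrilene HCl replicate 2 (0.862) and miR-99a highest in 2-acetylaminofluorene replicate 5 (0.742). Another 11 groups had more than 1 value at the floor, and the 8 groups of 3 animals were too small. Among miRNAs outside the tested set, miR-30c-1* was detected in 4 of 5 animals given 2-acetylaminofluorene and miR-874 in 3 of 5, against 0 control animals for both.

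miR-200a and miR-200b were higher with 6 chemicals, from log2 0.69 to 2.24 on the brightest probe of each. The other probe of miR-200a gave smaller differences with all 6, from 0.0835 with Diethylhexylphthalate to 1.24 with Phenobarbital. The 2 probes of miR-200b gave similar differences. With normexp none of these differences was called, and miR-200a was negative with Diethylhexylphthalate, Chlorendic Acid and Methapyrilene HCl. Low control animals stay open: 12 of 12 differences were also called higher against Diethylthiourea, but that group was chosen after it was seen to be the lowest, so this decides nothing. Low controls would shift every chemical alike, which argues against them as the whole cause with Phenobarbital. There miR-200a and miR-200b were at 2.08 and 2.24, against at most 1.12 and 1.23 with any other chemical. With slide as a block 12 of 12 were called, which argues against slide for the 5 chemicals other than Methapyrilene HCl. Methapyrilene HCl shares no slide with control. Its block values rest on slide differences estimated through the other chemicals, so they do not decide. With the number of detected miRNAs in the fit, as a measure of array brightness, 10 of 12 were called. That is fewer than the prediction fixed beforehand required to argue against brightness, so the test did not decide. For the 5 chemicals other than Methapyrilene HCl, set apart only after the result was seen, each difference was still called (0.64 to 2.225). With Methapyrilene HCl miR-200a went from 0.83 ± 0.22 (SE) to 0.73 ± 0.21 and miR-200b from 0.83 ± 0.22 to 0.80 ± 0.23, so the calls ended (adjusted p of 0.0262 and 0.0273 before, 0.0512 for each after) because they lay near the threshold, not because the differences vanished. A contribution of brightness, and an effect of the diets on these epithelial miRNAs, stay open as hypotheses.

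miR-34a was higher with Monuron, Chlorendic Acid, Methapyrilene HCl and 2-acetylaminofluorene. With slide as a block it was called in 4 of 4 (2.06, 1.25, 1.01 and 5.08). This argues against slide as the whole cause with Chlorendic Acid and 2-acetylaminofluorene. Monuron and Methapyrilene HCl share no slide with control. Their block values rest on slide differences estimated through the other chemicals, so they do not decide. Scaling is argued against as well, since at the lowest 4 of 4 were called under the 3 other scalings. A p53 response to these diets may be the reason, a hypothesis that was not tested. With normexp miR-34a was called only with 2-acetylaminofluorene. It was at -0.036 with Methapyrilene HCl, and it did not pass with Chlorendic Acid or Monuron (limma adjusted p = 0.983 and 0.815). That setting leaves the rises with Methapyrilene HCl, Chlorendic Acid and Monuron open.

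miR-193 and miR-324-3p were low with Chlorendic Acid but not in its replicate 4 (-3.17 and -1.90), and low in Monuron replicate 3 (-5.49 and -4.32, against -3.33 to -2.79 and -1.91 to -1.08 in the other 3 Monuron animals). A swap of the 2 arrays might explain this. Positions were taken over 30 other miRNAs that separate the groups, with 0 at the Monuron mean and 1 at the Chlorendic Acid mean. Chlorendic Acid replicate 4 lay at 0.382, between the groups. Monuron replicate 3 lay at 0.754, within the range of the other Chlorendic Acid arrays (0.747 to 1.26). The other Monuron arrays lay at -0.0935 to 0.112. A swap, a mixture and a difference between animals cannot be told apart. Low signal on Monuron replicate 3 is argued against as the whole cause: the 20 miRNAs nearest in level deviated by a median of -0.47 (SD 0.707), against -2.65 for these 2. The lowest of the 20 was at -2.52 and the array had the fewest detected miRNAs (90), so low signal as part of the cause stays open. No biological explanation was tested.

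Other splits of the same arrays were counted for each comparison, and chance is argued against where few of them called as many miRNAs as the real one. It is argued against for Diethylhexylphthalate (1 of 100 splits, the real one included, with 19 called and at most 14 in the others), Monuron (2 of 100, 5 and 5), Chlorendic Acid (1, 38 and 30), Methapyrilene HCl (1, 6 and 2) and 2-acetylaminofluorene (1, 15 and 11). The same holds for 2-acetylaminofluorene against the other 5 (1, 42 and 17) and any treatment (1, 58 and 2). The splits ignored slide. Monuron and Methapyrilene HCl share no slide with control, so for these 2 the splits do not separate diet from slide. Without Methapyrilene HCl replicate 4 its count was 0. For miRNAs called with at least 2 chemicals (1, 18 and 4) the redrawn labels remove every treatment effect, so they exclude a count of 18 without any effect but do not test whether separate lists overlap by chance, for which independent lists gave 11.9 higher and 1.43 lower. For Diethylthiourea the real count was 0, so its splits (100 of 100, 0 and 1) test nothing.

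Chance cannot be excluded in this way for Benzophenone (7 of 100, 6 and 19), the tumour-causing class (19 of 28, 8 and 42) or the lists (20 of 100, 8 and 22). Nor did the splits exclude it for Phenobarbital (4 of 56, 5 and 8), but the 3 other large splits each left all 3 Phenobarbital animals together on 1 side and so held the difference between the diets. For the 5 miRNAs called with Phenobarbital the values argue against chance: miR-200b was at -2.43 ± 0.137 (SD, n = 3) against -4.67 ± 0.18 (n = 5), and each call was kept without any 1 array and with slide as a block. The 6 other large splits for Benzophenone put control replicate 1 with Benzophenone replicates 2 and 5, and with up to 19 called they point to a structure of these samples, whose source was not tested. The split with 42, over 5 times the real count, sets Monuron and Chlorendic Acid apart from the other 6 chemicals and points to a structure of the samples. The splits that set Chlorendic Acid apart with another chemical called from 10 to 42 and those without it up to 33, and the source was not tested.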

How the results depend on the processing

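The alternatives without the 3 arrays with the fewest detected miRNAs (Monuron replicate 3, control replicate 1 and Diethylhexylphthalate replicate 2) and without Monuron replicate 3 and Chlorendic Acid replicate 4 were added after the data were seen. Of 176 alternative counts 128 stayed within 1.5 times and 48 moved. Of 2780 values of named miRNAs 2428 kept their direction and side of the threshold, 319 lost the call, 20 gained one and 13 changed sign, all 13 with normexp. Signal over background limits the dim miRNAs. The cause of the moves was not tested, except that fewer miRNAs were tested among those detected on all arrays, fewer animals with only the compared groups, and the normexp offset lies above the floor.

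With normexp the counts were 0 for Benzophenone, Phenobarbital and Methapyrilene HCl, 2 for Diethylhexylphthalate, 1 for Monuron, 7 for Chlorendic Acid, 3 for 2-acetylaminofluorene, 1 for the tumour-causing class, 7 for 2-acetylaminofluorene against the other 5, 8 for any treatment and 1 for miRNAs called with at least 2 chemicals. The sign changed for miR-182 with Benzophenone (-0.0065), for miR-96 (-0.071), miR-200a (-0.067), miR-93 (-0.0092) and miR-375 (-0.16) with Diethylhexylphthalate, miR-375 with Monuron (-0.027), miR-139-5p (-0.0068), miR-200a (-0.12), miR-186 (-0.081) and miR-181a (-0.22) with Chlorendic Acid, and miR-34a (-0.036), miR-200a (-0.045) and miR-93 (-0.096) with Methapyrilene HCl, with adjusted p from 0.571 to 0.991. Of 85 named calls, 56 more lost the call.

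Among the 80 miRNAs detected on all arrays the counts were 1 for Benzophenone, 0 for Phenobarbital, 11 for Diethylhexylphthalate, 1 for Monuron, 18 for Chlorendic Acid, 1 for Methapyrilene HCl, 6 for 2-acetylaminofluorene, 2 for the tumour-causing class, 19 for 2-acetylaminofluorene against the other 5, 36 for any treatment, 0 for the lists and 2 for miRNAs called with at least 2 chemicals.

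Scaling over all probes gave 7 for Diethylhexylphthalate, 1 for Methapyrilene HCl, 53 for 2-acetylaminofluorene, 5 for the tumour-causing class and 64 for 2-acetylaminofluorene against the other 5. Quantile normalization gave 10 for Methapyrilene HCl and 4 for the lists, the total gene signal 12 for Methapyrilene HCl and 14 for the tumour-causing class, and the authors' table gave 33 for 2-acetylaminofluorene and 13 for the tumour-causing class. Of the 85 named calls 20 were lost with scaling over all probes, 16 with the authors' table, 13 with quantile normalization, 9 with the mean of probes, 7 with the total gene signal, 6 with no filter and 1 with the lower floor. miR-122 ranks first on every array, so quantile normalization fixes its difference at 0.

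With slide as a block the counts were 11 for Diethylhexylphthalate, 3 for Monuron, 3 for Methapyrilene HCl, 5 for 2-acetylaminofluorene, 24 for 2-acetylaminofluorene against the other 5 and 8 for miRNAs called with at least 2 chemicals, and 23 named calls were lost. In fits of only the compared groups they were 2 for Benzophenone, 3 for Monuron, 21 for Chlorendic Acid, 8 for 2-acetylaminofluorene and 8 for miRNAs called with at least 2 chemicals, and 25 named calls were lost. With replicate number as a block, which the labels do not say pairs the animals, no count moved by over 1.5 times (5 for Methapyrilene HCl) and 2 named calls were lost. Camera with an estimated correlation gave 1 list. Without the 3 arrays with the fewest detected miRNAs the counts were 11 for Diethylhexylphthalate and 3 for Methapyrilene HCl.

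With each array left out in turn the counts ran from 0 to 0 for Diethylthiourea, 6 to 12 for Benzophenone, 5 to 6 for Phenobarbital, 8 to 18 for Diethylhexylphthalate, 3 to 6 for Monuron, 26 to 44 for Chlorendic Acid, 0 to 7 for Methapyrilene HCl, 10 to 17 for 2-acetylaminofluorene, 5 to 12 for the tumour-causing class, 20 to 44 for 2-acetylaminofluorene against the other 5, 50 to 68 for any treatment, 6 to 9 for the lists and 12 to 20 for miRNAs called with at least 2 chemicals. Moved by over 1.5 times were Benzophenone without its replicate 1 (12), Diethylhexylphthalate without its replicate 1 (8) or 2 (12), Monuron without its replicate 3 (3), the tumour-causing class without Diethylthiourea replicate 1 (5) and the comparison of 2-acetylaminofluorene with the other 5 without its replicate 3 (20). Methapyrilene HCl moved without control replicate 1 (3) or 2 (1) and without its replicate 1 (2), 3 (1) or 4 (0).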

Other observations

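The chemicals were also compared with one another, a set of tests chosen only after the data were seen. miR-96 was higher with Phenobarbital than with Chlorendic Acid by log2 2.47 (adjusted p = 4.67e-13), and miR-221 was lower with Benzophenone than with Diethylhexylphthalate, at -2.36 (adjusted p = 5.06e-12). miR-34a was higher with Monuron than with Chlorendic Acid by 0.79 (adjusted p = 0.0186) and than with Methapyrilene HCl by 1.07 (adjusted p = 0.00303), and with Methapyrilene HCl it was at -4.10 relative to 2-acetylaminofluorene (adjusted p = 6.53e-17). miR-107 was higher with Diethylhexylphthalate than with 2-acetylaminofluorene by 1.18 (adjusted p = 2.2e-10). miR-200b was higher with Phenobarbital than with Monuron by 1.93, Methapyrilene HCl by 1.41, Diethylhexylphthalate by 1.31, Chlorendic Acid by 1.12 and 2-acetylaminofluorene by 1.1. Between Methapyrilene HCl and 2-acetylaminofluorene 2 miRNAs differed, and between Chlorendic Acid and 2-acetylaminofluorene 33 were higher and 24 lower.

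Across the 129 miRNAs, which are not independent replicates, the differences from control correlated by 0.67 between Chlorendic Acid and Methapyrilene HCl, 0.651 between Monuron and Chlorendic Acid and 0.649 between Benzophenone and Phenobarbital. Groups with no effect set against the same control animals gave 0.46, 0.438 and 0.406 for these pairs. Setting each chemical of a pair against a separate part of the control animals gave 0.452, 0.443 and 0.354. Diethylhexylphthalate and 2-acetylaminofluorene correlated by 0.0113, against 0.436 for groups with no effect and -0.0821 with different control animals. Groups with no effect lack the variance that effects add, so their correlations are not the level expected of real profiles. For Chlorendic Acid and 2-acetylaminofluorene the correlation was below theirs (0.205 against 0.482), while the covariance was above it (0.063 against 0.021).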
